A study of Saccharomyces cerevisiae with 17 samples.

How the data were processed

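RNA sequencing was carried out on 17 libraries of Saccharomyces cerevisiae from 3 experiments, each library made from its own culture. By the growth protocol an overnight culture was used to start a culture for each phosphate level, so libraries with and without phosphate can share a parent culture, which the tests of the phosphate response do not take into account. Per the labels' protocols, RNA was purified with a commercial yeast kit, libraries were made with a stranded kit from mRNA, amplified by PCR and sequenced on an Illumina HiSeq instrument. The values used here are RPM, reads scaled to the library total, for 7125 named features, deposited by the authors in 1 table; the aligner, the counter, the genome build and whether strand was used in counting are not given in the sources used here. Each library's RPM values were whole multiples of the value of a single read, and at a tolerance of 0.001 reads 100% of them came out whole, so read numbers per feature could be recovered. The recovered depth ran from 17456154 to 44667485 reads per library, which put the level equal to 3 reads between 0.0672 and 0.172 RPM. Intervals of ratios of reads, and the floors, cover counting error only, since PCR copies of a molecule are not independent.

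Groups were taken from the sample labels. The description of the series states independent cultures, and p-values measure the spread between these cultures. For the spl2 deletion strain that description gives 3 cultures with phosphate and 2 without, whereas the sample labels give 2 and 3; the sample labels were used. Each library was counted as 1 replicate on the basis of that description. No pair of libraries of a group agreed within sampling noise (mean chi-square per gene 3.84 to 26.9), which does not by itself show separate cultures.

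The design written before the data were examined named a count test for read counts and limma for normalized values. Because the table holds RPM, the test was limma 3.58.1 (R 4.3.3) with an intensity trend on log2(RPM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. A feature was tested where it reached 1 RPM in at least as many libraries as the smaller of the compared groups held, and in no fewer than 2. Fold changes are on the log2(RPM + 1) scale, which understates the change of features with low values; folds without a log are ratios of mean RPM. The 12 libraries of experiment 1 entered 1 model with a mean per group, and the rrp6 comparison used a model of the 15 libraries of experiments 1 and 2 with the contrast kept within experiment 2. Residual degrees of freedom were 7 and 8. Where a group held 1 library, that library was assumed to vary like the other groups. The promoter pair of experiment 3 has 1 library per group, so it was described by log2 ratios of RPM + 1 with no test, and by ratios of reads with exact 95% intervals.

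Gene lists, 30 in all, were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists with at least 3 tested members, and again with an estimated correlation and with fry. Fry tests whether the genes of a list move, on balance, in 1 direction, and does not compare the list with other genes. For the promoter pair the median of a list was placed among those of 10000 random lists of the same size matched on mean level. Genes were named by a rule fixed beforehand. For each comparison it took SPL2, BMH1, RRP6, PHO84, PHO5, PHO87 and PHO90, then the 10 highest and 10 lowest changes among genes that passed, reached a mean of 10 RPM and had groups that did not overlap, and up to 4 members of each list with the largest changes that passed. For the promoter pair the minimum was 30 RPM. Features of the ribosomal DNA repeat that this rule reached were left out of the named genes, because reads of repeated copies cannot be assigned. Values of other multi-copy, overlapping or antisense features are uncertain, because the sources do not say how such reads were counted.

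The fitting step was tested on simulated data in which 200 genes with at least 10 RPM were changed, 100 of them 1.5-fold and 100 of them 2-fold. Of the genes changed 1.5-fold it recovered 100% in BY4741 without phosphate (5985 genes), 100% in the spl2 deletion without phosphate (6004 genes) and 100% for the spl2 deletion at 7.2 mM (5993 genes). The recovery was 98% for the spl2 deletion at 0 mM (6035 genes), 95% for the strain difference (6036 genes), 97% for the bmh1 deletion (5987 genes) and 99% for the rrp6 deletion (5937 genes). Of the genes changed 2-fold it recovered 99% for the strain difference and 100% in each of the other 6. False calls made up 4.31%, 4.76%, 2.44%, 6.6%, 4.43%, 5.74% and 2.93% of all calls in the same order. The simulated changes were balanced between higher and lower, with genes drawn independently and without a batch or a shift of the median gene. Some comparisons below show such shifts, so these shares do not give the false calls made in the data.

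Other settings fixed before the data were examined were a pseudocount of 0.1 or 5, no filter, a fit of the compared groups alone and leaving out each library in turn. Chosen after seeing the data were RPM scaled by TMM factors in the same limma model, the quasi-likelihood test of edgeR 4.0.16 and the Wald test of DESeq2 1.42.0 on the recovered reads, the BY4741 library of experiment 2 as the reference for the bmh1 deletion, the range of the BY4741 libraries of all experiments for the named genes of the bmh1, rrp6 and promoter strains, and camera without SPL2 where that gene was deleted. Of the 7125 features, 6211 were matched by name to the yeast reference R64 (GCF_000146045.2), which served only for names and for which genes neighbour each other. No coordinates are given, because no build is named for the table. 1 line of the table is not reported here.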

Results

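Transcript levels of Saccharomyces cerevisiae were measured in 17 libraries, in a study of how phosphate genes are controlled in single yeast cells by 14-3-3 protein, Spl2 and alternative transcription. All strains were derived from BY4741, a haploid laboratory strain of mating type a that lacks several biosynthetic genes. Cultures grown with 7.2 mM phosphate were washed and kept for 60 min with 7.2 mM or 0 mM phosphate. Experiment 1 held 3 BY4741 libraries at each phosphate level, 2 libraries of an spl2 deletion at 7.2 mM, 3 of the same strain at 0 mM, and 1 of a bmh1 deletion at 7.2 mM. Experiment 2 held 1 BY4741 and 2 rrp6 deletion libraries, and experiment 3 held 1 BY4741 library and 1 of a strain lacking a segment of the SPL2 promoter called block P, all at 7.2 mM. For the spl2 deletion the description of the series and the sample labels differ on which phosphate level had 3 cultures, and the labels were followed. Recovered depth ran from 17456154 reads in an rrp6 deletion library to 44667485 in BY4741 of experiment 3.

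The deleted genes followed the labels. SPL2, which encodes a small protein that acts on low-affinity phosphate uptake, stood at 20.6 ± 0.4 RPM (reads scaled to the library total) in BY4741 at 7.2 mM (SD, n = 3). It had 0 reads in both spl2 deletion libraries at 7.2 mM, a level at least 165-fold lower than in BY4741 against a floor of 3 reads per library. At 0 mM the spl2 deletion libraries 12, 19 and 20 held 0, 8 and 1 SPL2 reads, a mean of 0.0782 RPM against 296.8 ± 10.6 RPM in BY4741 (SD, n = 3). BMH1, which encodes a 14-3-3 protein, fell from a mean of 996.2 RPM in BY4741 to 1.46 RPM (46 reads) in the bmh1 deletion library, a level 681-fold lower. RRP6, which encodes the exonuclease subunit of the nuclear exosome, had 0 reads in both rrp6 deletion libraries and 57.8 RPM in BY4741 of the same experiment, so that it was at least 337-fold lower against the floor of 3 reads per library. LEU2, MET17 and URA3, which are deleted in BY4741, had 0 reads in all 17 libraries. HIS3, of which BY4741 lacks a part, stood at 158 to 223 RPM, so reads of that gene do not show its partial deletion.

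The first comparison asked how BY4741 responded to 60 min without phosphate. Genes of the PHO regulon, which Pho4 activates when phosphate is scarce, rose most. PHO84, the high-affinity phosphate transporter, rose from 193.1 ± 3.98 to 2227 ± 61.7 RPM (SD, n = 3 and 3), 11.5-fold. PHO5, a secreted acid phosphatase, rose 15.2-fold to 516.4 ± 22.1 RPM, and SPL2 rose 14.4-fold. In all, 21 of the 22 tested members of the regulon rose and none fell, and the same 21 rose when adjusted over the list alone. The log2 fold changes of PHO84, PHO5 and SPL2 were 3.52 ± 0.0534, 3.89 ± 0.102 and 3.79 ± 0.0819 (SE), with limma adjusted p of 1.94e-16, 1.3e-13 and 1.45e-14. The other members with the largest changes were PHM6 at 4.01, the sodium-coupled phosphate transporter PHO89 at 3.90, the acid phosphatases PHO11 at 3.71 and PHO12 at 3.52, and the polyphosphate synthesis genes VTC3 at 2.95 and VTC4 at 2.47. ARO9, an aromatic aminotransferase gene that neighbours SPL2 in the reference, rose 7.57-fold from 9.31 ± 0.459 to 70.4 ± 3.32 RPM (SD, n = 3 and 3). Among genes of phosphate signalling, the inositol pyrophosphate kinase genes VIP1 and KCS1 rose by log2 1.15 ± 0.0518 and 0.77 ± 0.0489, and the inositol polyphosphate hydrolase gene DDP1 by 0.85 ± 0.0481 (SE).

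Other groups moved in BY4741 as well. Of 37 general stress genes 36 rose and none fell (36 when adjusted over the list alone), with the membrane protein gene HSP12 rising 3.88-fold to 815.9 ± 114 RPM (SD, n = 3). DDR2, RTC3 and SOL4 of the same list rose by log2 1.35, 1.34 and 1.30. The glycolytic genes TDH1 and ENO1 rose by 1.95 ± 0.0903 and 1.52 ± 0.069 (SE). Of 137 ribosomal protein genes 123 fell and 1 rose (124 and 1 when adjusted over the list alone), RPS26B, RPS9B and RPL20A by the most, with log2 fold changes of -0.56, -0.55 and -0.55. Ribosomal protein genes took 30.1% to 33.3% of reads with phosphate and 24.4% to 26.3% without. Of 16 purine synthesis genes 13 fell (13 when adjusted over the list alone), among them the serine hydroxymethyltransferase gene SHM2 at -0.45, GCV3 at -0.39 and ADE1 at -0.36. RIB4, a riboflavin synthesis gene, had the largest fall at -0.91 ± 0.0627, followed by the siderophore transporter gene SIT1 at -0.86, the hexose transporter gene HXT4 at -0.86, the iron oxidase gene FET3 at -0.82 and the pyrimidine synthesis gene URA1 at -0.75. Of 19 iron genes 9 fell and 2 rose (9 and 2 when adjusted over the list alone). Of 31 amino acid genes under Gcn4 control 13 fell and 3 rose (13 and 2 when adjusted over the list alone), ARG3 and ARG8 by the most at -0.74 and -0.61. Of the low-affinity transporter genes, PHO87 rose by 0.52 ± 0.0649 and PHO91 by 0.39 ± 0.0567, while PHO90 stood at -0.05 ± 0.0507 (SE; limma adjusted p = 0.396), and at -0.26 after TMM scaling (adjusted p = 0.000154).

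In total 4068 of 6015 genes passed the test in BY4741, 3666 higher and 402 lower without phosphate. Of these, 76 rose at least 2-fold while 0 fell as far, against 36 and 4 of the genes called after TMM scaling. The median gene was 0.21 higher on the log2 scale of RPM and 0.00666 higher after TMM scaling, which called 2311 genes, 1084 higher and 1227 lower (46.9% higher against 90.1%). Relative to the median gene, the list medians were 1.80 for the PHO regulon, 0.69 for general stress, -0.55 for ribosomal proteins, -0.49 for purine synthesis, -0.36 for iron genes and -0.32 for Gcn4 genes. After TMM scaling 21 PHO genes rose and 1 fell, 35 stress genes rose, and 128 ribosomal protein, 16 purine, 23 Gcn4 and 11 iron genes fell, with no gene of these last 4 lists higher. Ribosome biogenesis genes were 2 higher and 8 lower of 59 on the RPM scale, 1 and 3 when adjusted over the list alone, but 1 higher and 52 lower after TMM scaling. With camera the limma-based adjusted p was 2e-17 for the PHO regulon, 4.82e-98 for ribosomal proteins, 3.2e-20 for purine synthesis, 3.31e-12 for general stress, 1.26e-10 for iron, 1.89e-13 for Gcn4 and 6.55e-13 for ribosome biogenesis genes. The PHO regulon, the ribosomal proteins and the purine genes held with an estimated correlation (adjusted p = 0.0195 for each), as did the PHO regulon at 7.2 mM in the spl2 deletion below with SPL2 included but not without it, and no other list call of any comparison did. For BY4741 the others had adjusted p = 0.157 for general stress, 0.215 for iron, 0.306 for Gcn4 and 0.41 for ribosome biogenesis genes with an estimated correlation.

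**Figure D1:**
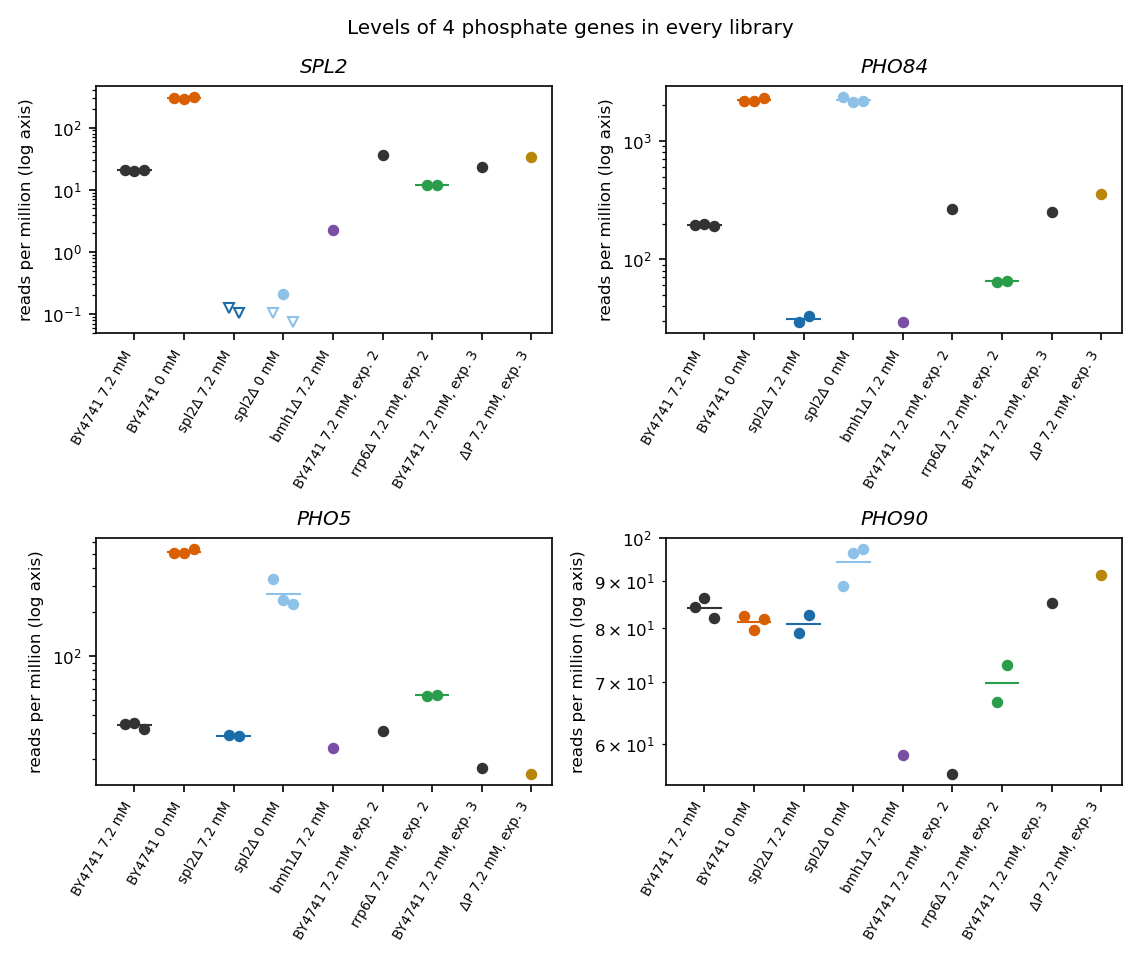
RPM on a log axis for SPL2, PHO84, PHO5 and PHO90 in each of 17 libraries, with points for libraries, short lines for means of groups with more than 1 library, and open triangles at the 3-read floor for libraries below it. PHO84 lay between 2151 and 2346 in all 6 libraries at 0 mM, and between 29.2 and 33.1 in the spl2 and bmh1 deletion libraries at 7.2 mM, while PHO90 stayed between 55.8 and 97.4 in all 17.

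The same change of medium was examined in the spl2 deletion strain. PHO84 rose 71.4-fold, from 31.2 ± 2.6 RPM (SD, n = 2) to 2231 ± 103 RPM (SD, n = 3), a log2 fold change of 6.12 ± 0.0597 (SE; limma adjusted p = 2.32e-19). All 21 PHO regulon members other than SPL2 rose (21 when adjusted over the list alone, 19 after TMM scaling). PHO12 rose 23.7-fold, PHM6 by log2 4.36 ± 0.121, VTC3 by 4.17 ± 0.0739 and PHO89 by 3.97 ± 0.129 (SE). PHO11, VTC4 and PHO5 rose by 3.87, 3.28 and 3.16, and the polyphosphate gene VTC1 and the kinase inhibitor gene PHO81 by 2.18 and 2.17. PHO5 reached 267.6 ± 58.4 RPM (SD, n = 3), and ARO9 reached 28.2 ± 1.85 RPM, a 4.03-fold rise. VIP1 rose by log2 1.48 and PHO87 by 0.83 ± 0.0726 (SE), while PHO90 rose by 0.22 ± 0.0567 on the RPM scale but stood at -0.01 after TMM scaling.

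Ribosomal protein genes fell in this strain too, 126 of 137 with 1 higher (128 and 1 when adjusted over the list alone), and RPL25 had the largest fall of the list at -0.87 ± 0.0934 (SE). Of 59 ribosome biogenesis genes 55 rose (55 when adjusted over the list alone), with UTP21 at 0.91 and the RNA helicase gene DBP7 at 0.59, and after TMM scaling 36 rose and 3 fell. General stress genes split into 24 that rose and 3 that fell of 37 (24 and 3 when adjusted over the list alone), and into 7 and 7 after TMM scaling. HSP12 rose 1.67-fold and YGP1 by log2 0.65, whereas the glycogen synthase gene GSY1 fell by 0.64 and the cytochrome c isoform gene CYC7 fell by 0.61. RIB4 was at -0.95 and the mating type a gene ASG7 at -0.89. Larger falls were listed for the uncertain reading frames BUD28 at -1.40, OPI11 at -1.03 and YBR012C at -0.95. In total 3984 of 6033 genes passed, 3456 higher and 528 lower, with a median shift of 0.23 on the RPM scale and 0.00894 after TMM scaling, which called 1269 higher and 1400 lower (47.5% higher against 86.7%). Relative to the median gene the list medians were 1.76 for the PHO regulon, -0.68 for ribosomal proteins, 0.19 for ribosome biogenesis and 0.05 for general stress. Camera gave limma-based adjusted p of 6.83e-16, 6.28e-83, 7.9e-05 and 0.846 for them, and the first 3 had adjusted p = 0.051, 0.051 and 0.75 with an estimated correlation.

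The difference between these responses was tested as an interaction, spl2 deletion minus BY4741. PHO84 responded more strongly in the spl2 deletion by log2 2.60 ± 0.0799 (SE; limma adjusted p = 9.7e-12), as did VTC3 by 1.23 ± 0.099, PHO12 by 0.98 ± 0.152 and VTC4 by 0.81 ± 0.0693. PHO5 responded less, with a difference of -0.74 ± 0.153 (adjusted p = 0.00565), and so did ARO9, the neighbour of the deleted SPL2, with -0.92 ± 0.112. General stress genes responded less in the spl2 deletion, 34 of 37 with none in the other direction (36 when adjusted over the list alone, 34 after TMM scaling). HSP12 differed by -1.22 ± 0.152, RTC3 by -1.09 ± 0.109, CYC7 by -1.08 ± 0.116 and the plasma membrane protein gene HOR7 by -1.01 ± 0.161. Ribosome biogenesis genes responded in the other direction, 51 of 59 higher and none lower (56 when adjusted over the list alone), among them the RNA helicase gene DBP2 at 0.69, the nucleolin gene NSR1 at 0.64, ENP2 at 0.60 and UTP10 at 0.59. Of 16 purine synthesis genes 9 were higher (12 when adjusted over the list alone), with SHM2 at 0.45 and ADE6 at 0.42. The transporter genes PHO87 and PHO90 differed by 0.30 ± 0.0974 (adjusted p = 0.0484) and 0.27 ± 0.076 (adjusted p = 0.0291), and AQR1, a multidrug transporter gene, by 0.84. Of the 21 PHO regulon members other than SPL2, 6 were higher and 3 lower (7 and 3 when adjusted over the list alone).

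The interaction passed for 882 of 6071 genes, 413 higher and 469 lower. Camera called the stress list (limma-based adjusted p = 3.66e-26, and adjusted p = 0.117 with an estimated correlation), ribosome biogenesis (5.85e-28 and 0.361) and purine synthesis (2.18e-07 and 0.245). For the PHO regulon the adjusted p was 0.0877 with the deleted SPL2 included and 0.0161 without it (adjusted p = 0.605 with an estimated correlation). The number of genes was 506 without BY4741 library 16 at 0 mM, 508 without spl2 deletion library 7 and 537 without spl2 deletion library 19. On the RPM scale 75 of the 6000 genes tested in both strains other than SPL2 rose at least 2-fold in BY4741. In the spl2 deletion 46 did, and 34 rose as far in both strains, where independent lists would share 0.575.

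**Figure D2:**
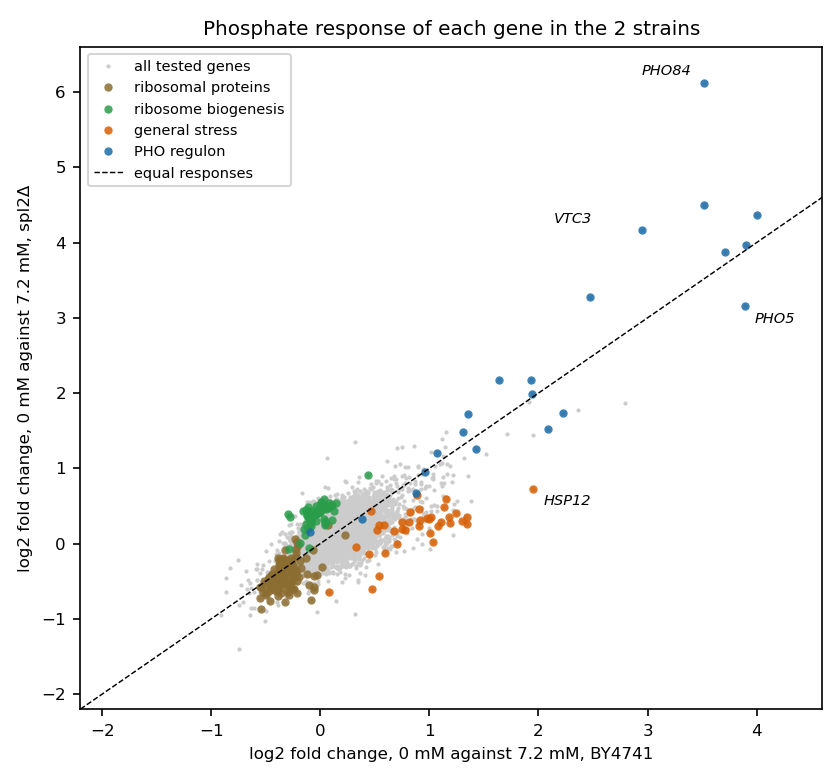
Log2 fold change of each gene at 0 mM against 7.2 mM phosphate, BY4741 on the horizontal and the spl2 deletion on the vertical axis, with members of 4 lists coloured, SPL2 left out and a dashed line where both responses are equal. Most general stress genes lie below the line (HSP12 at 1.95 and 0.73), and PHO84 lies above it (3.52 and 6.12).

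At 7.2 mM phosphate the spl2 deletion strain had lower levels of several PHO genes than BY4741. PHO84 was 6.18-fold lower, at 31.2 ± 2.6 RPM (SD, n = 2) against 193.1 ± 3.98 RPM (SD, n = 3), a log2 fold change of -2.59 ± 0.0599 (SE; limma adjusted p = 4.8e-14). PHO12 was 2.39-fold, VTC3 2.31-fold, PHM6 2.39-fold, PHO11 1.81-fold and VTC4 1.73-fold lower, with log2 fold changes of -1.23, -1.20, -1.12, -0.82 and -0.78. Of the 21 tested PHO regulon members other than SPL2, 12 fell and none rose (12 when adjusted over the list alone, 10 after TMM scaling). PHO5 did not pass at 28.7 ± 0.481 against 33.9 ± 1.63 RPM (SD; log2 fold change -0.23 ± 0.114 SE, adjusted p = 0.4), nor did PHO87 at -0.26 ± 0.0726 (adjusted p = 0.142) or PHO90 at -0.06 ± 0.0568 (adjusted p = 0.686). Of 37 general stress genes 7 were higher and none lower past the test (30 higher when adjusted over the list alone). They were led by CYC7 at 0.53 ± 0.0868, RTC3 at 0.51 ± 0.0813, SOL4 at 0.42 ± 0.0732 and the ATPase stabilising factor gene STF2 at 0.37 ± 0.0593. The nicotinamidase gene PNC1 was higher by 0.37. No ribosome biogenesis gene passed over all genes, although 45 of 59 were lower when adjusted over the list alone. YGR109W-B, a gene of the repeated Ty3 element whose reads are uncertain, was 5.91-fold higher, and the unnamed feature YIL080W was 1.73-fold lower.

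In all 30 of 6002 genes passed, 13 higher and 17 lower, and 21 higher and 15 lower after TMM scaling (58.3% against 43.3% higher). Camera gave a limma-based adjusted p of 4.52e-23 for the PHO regulon with the deleted SPL2 included and 3.44e-19 without it (adjusted p = 0.025 and 0.0564 with an estimated correlation), 3.23e-26 for general stress (adjusted p = 0.0565 with an estimated correlation) and 3.33e-21 for ribosome biogenesis (adjusted p = 0.454 with an estimated correlation). The count was 51 without BY4741 library 10, 16 without BY4741 library 13, 17 without spl2 deletion library 7 and 65 without spl2 deletion library 18, and it was 81 in a fit of the compared groups alone and 112 with DESeq2.

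At 0 mM phosphate PHO84 no longer differed detectably between the strains, at 2231 ± 103 RPM in the spl2 deletion and 2227 ± 61.7 RPM in BY4741 (SD, n = 3 and 3; log2 fold change 0.00 ± 0.0534 SE, limma adjusted p = 0.987). Other PHO genes were lower in the spl2 deletion. PHO5 was 1.93-fold lower with a log2 fold change of -0.97 ± 0.102 (SE; adjusted p = 5.59e-05), PHO89 was at -0.84 ± 0.115 and PHM6 at -0.76 ± 0.109. Of the 21 PHO regulon members other than SPL2, 9 fell and none rose (10 lower and 1 higher when adjusted over the list alone). ARO9, the neighbour of the deleted SPL2, was 2.5-fold lower, and TDH1 was at -0.54 ± 0.0903 (SE). Of 37 general stress genes 28 fell and none rose (33 when adjusted over the list alone), HSP12 from 815.9 ± 114 to 454.4 ± 45.2 RPM (SD, n = 3 and 3), with HSP26 at -0.60, HOR7 at -0.58 and RTC3 at -0.58. Ribosome biogenesis genes were higher, 42 of 59 with none lower (52 when adjusted over the list alone), among them DBP2 at 0.41, UTP10 at 0.40, NSR1 at 0.38 and the RNA polymerase I subunit gene RPA190 at 0.37. Purine synthesis genes were higher for 8 of 16 (12 when adjusted over the list alone), with ADE6 at 0.40, ADE5,7 at 0.28 and SHM2 at 0.27. IMD2 and URA2, nucleotide synthesis genes, were higher by 0.43 and 0.42, and FET3 by 0.39. PHO90 was higher by 0.21 ± 0.0507 (adjusted p = 0.0153), whereas PHO87 was at 0.04 ± 0.065 (adjusted p = 0.713). YGR109W-B was 5.64-fold higher and YIL080W 1.66-fold lower.

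In total 789 of 6031 genes passed at 0 mM, 340 higher and 449 lower, and 492 higher and 463 lower after TMM scaling, so that the larger share changed side (43.1% and 51.5% higher). Camera gave limma-based adjusted p of 1.51e-20 for general stress, 4.05e-26 for ribosome biogenesis, 2.88e-08 for purine synthesis and 1.86e-05 for the PHO regulon with SPL2 included, and adjusted p = 0.188, 0.302, 0.188 and 0.268 with an estimated correlation. Without SPL2 the PHO regulon had 0.00081, and adjusted p = 0.368 with an estimated correlation. The count was 369 without BY4741 library 14, 228 without BY4741 library 16, 282 without spl2 deletion library 19 and 474 without spl2 deletion library 20.

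The bmh1 deletion was measured in 1 library at 7.2 mM and compared with the 3 BY4741 libraries of experiment 1, and, as a second reference chosen after seeing the data, with the BY4741 library of experiment 2. The difference from that single library has no replicates on either side, so it is given as a value without a test. PHO84 stood at 29.2 RPM, 6.6-fold lower than in BY4741 of experiment 1, with log2 fold changes of -2.68 ± 0.0758 (SE; limma adjusted p = 1.02e-12) against the first reference and -3.13 against the second. SPL2 stood at 2.26 RPM (71 reads), 9.12-fold lower, with -2.73 ± 0.117 (SE) and -3.51. The 5 BY4741 libraries at 7.2 mM of all 3 experiments ranged from 189.1 to 263.4 RPM for PHO84 and from 20.21 to 36.08 RPM for SPL2. Of 22 PHO regulon genes 17 fell and 1 rose against the first reference (17 and 1 when adjusted over the list alone, 13 and 2 after TMM scaling), and the list median against the second reference was -0.71. VTC3 was at -1.41 and -1.48, and PHM6 at -1.47 and -1.97. PHO5 was at -0.51 ± 0.144 (limma adjusted p = 0.00593), but did not pass after TMM scaling at -0.29 (adjusted p = 0.145), and its value against the second reference was -0.38. PHO87 was at -0.66 and -0.19, and PHO90 was at -0.52 against the first reference and on the other side at 0.07 against the second.

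Other genes that changed against the first reference, followed by their value against the second, included HXT4 at -1.82 and -1.71, the cold-shock cell wall gene TIR1 at -1.80 and -1.73, the flavohaemoglobin gene YHB1 at -1.59 and -1.55, the glycogen genes GSY1 at -1.43 and -1.56 and GPH1 at -1.41 and -1.48, and the siderophore transporter gene ENB1 at -1.13 and -1.40. NCE103, the carbonic anhydrase gene, was higher by 1.70 and 1.56, RPL41A by 1.22 and 1.32, HOR7 by 1.07 and 0.80 and the histone gene HHT1 by 0.77 and 0.88. Of 37 general stress genes 27 fell and 3 rose against the first reference (27 and 3 when adjusted over the list alone, 17 and 6 after TMM scaling), and the list median against the second was -0.79. Of 19 iron genes 16 fell and 1 rose (16 and 1 when adjusted over the list alone, 10 and 1 after TMM scaling), with a median of -0.52 against the second reference. Of 8 core histone genes 6 rose (6 when adjusted over the list alone, 8 after TMM scaling), with a median of 0.51 against the second, and 6 of 7 hexose transporter genes fell (6 when adjusted over the list alone, 5 with 1 higher after TMM scaling), with a median of -0.49. Ribosomal protein genes were 91 higher and 9 lower of 137 against the first reference (94 and 11 when adjusted over the list alone, 119 and 2 after TMM scaling), but their median was 0.28 against the first and on the other side at -0.0123 against the second. Ribosome biogenesis genes were 48 lower and 1 higher of 59 against the first (50 and 1 when adjusted over the list alone, 41 and 5 after TMM scaling), with a median of -0.57, and on the other side at 0.22 against the second. HSP12 was 2.98-fold higher than in the first reference, with log2 fold changes of 1.58 and 0.49 against the first and second. The Ty3 gene YGR109W-B was at -2.77, and at -0.79 against the second reference. BMH2, the other 14-3-3 gene, was at -0.38 against the first reference and on the other side at 0.07 against the second. The levels of RPL41A, HOR7, PHO5, PHO90, BMH2 and YGR109W-B in the bmh1 deletion library lay within those of the 5 BY4741 libraries, and the other genes named here lay outside them.

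Against the first reference 3832 of 5987 genes passed, 908 higher and 2924 lower, with a median shift of -0.22 that TMM scaling reduced to 0.000334 (1776 higher and 1693 lower, 51.2% against 23.7% higher). Relative to that median gene the list medians were -0.44 for the PHO regulon (limma-based camera adjusted p = 0.00141, and adjusted p = 0.579 with an estimated correlation), 0.55 for core histones (9.06e-05 and 0.579), 0.50 for ribosomal proteins (3.03e-23 and 0.579), -0.35 for ribosome biogenesis (7.82e-05 and 0.776) and -0.24 for iron genes (0.0421 and 0.779). Camera did not call general stress (0.108) or hexose transporter genes (0.0903). Of the 3832 genes 958 kept at least 50% of their log2 change in the same direction against the second reference, 337 higher and 621 lower, and 1713 had a value in the opposite direction.

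**Figure D3:**
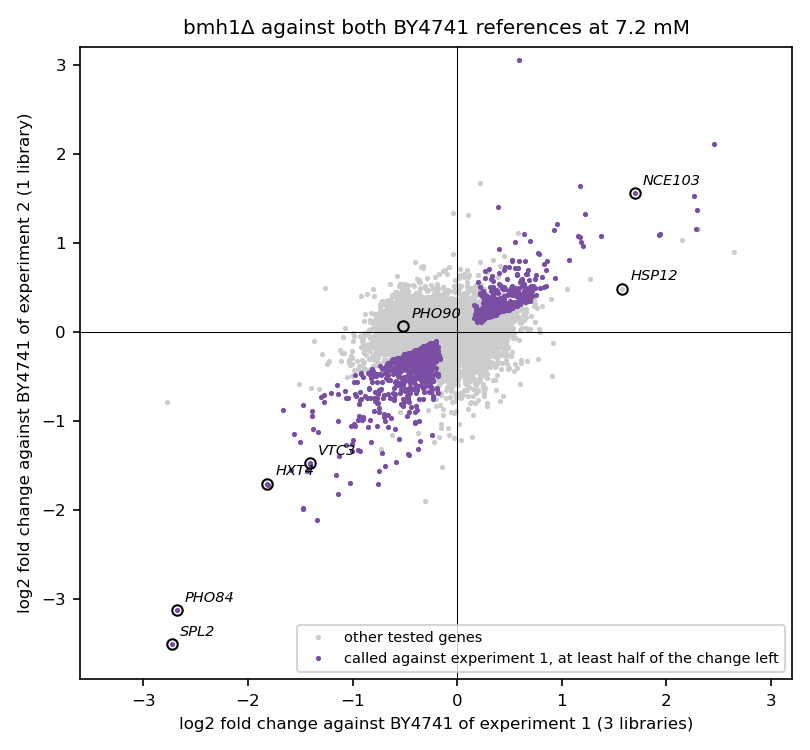
Log2 fold change of each gene in the bmh1 deletion library at 7.2 mM against BY4741 of experiment 1 (horizontal axis, 3 libraries) and against BY4741 of experiment 2 (vertical axis, 1 library), with purple for the genes that passed against experiment 1 and kept at least 50% of the change in the same direction against experiment 2, and BMH1 left out. PHO84 and SPL2 lie at the lower left (-2.68 and -3.13, -2.73 and -3.51), while HSP12 and PHO90 lie closer to 0 on the vertical axis (0.49 and 0.07).

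The effect of losing the nuclear exosome subunit was examined at 7.2 mM in experiment 2, with 2 rrp6 deletion libraries and 1 BY4741 library. Reads of the U3 small nucleolar RNA genes SNR17A and SNR17B rose 47.9-fold and 50.1-fold, to 168 and 107.2 RPM. The log2 fold changes were 5.23 ± 0.224 and 5.11 ± 0.188 (SE, limma adjusted p = 9.51e-12 and 1.54e-12). Only 2 of 81 small nucleolar RNA features were tested here. The libraries were made from mRNA, so these reads need not give the amount of mature U3 RNA. EFM3, a lysine methyltransferase gene, rose 51.1-fold to 415 RPM. The unnamed reading frames YJL047C-A and YPR092W rose from 1.04 and 0.535 RPM to 198.1 and 63.1 RPM. Against these rises PHO84 fell 4.07-fold, to 64.7 ± 0.285 RPM (SD, n = 2) from 263.4 RPM, a log2 fold change of -2.01 ± 0.0777 (SE; adjusted p = 2.34e-12). SPL2 was 3.03-fold lower at 11.9 ± 0.261 RPM (SD, n = 2), PHO12 3.03-fold lower and VTC3 2.71-fold lower. The BY4741 library of this experiment had the highest PHO84 and SPL2 of the 5 BY4741 libraries at 7.2 mM, and against the lowest of these PHO84 was 2.92-fold and SPL2 1.7-fold lower. PHO5 went the other way, 1.74-fold higher at 54.0 ± 0.746 RPM (SD, n = 2) with a log2 fold change of 0.78 ± 0.148 (SE), and PHO90 was higher by 0.32 ± 0.0801 but, at 66.5 and 73.1 RPM, within the 55.8 to 86.3 RPM of the 5 BY4741 libraries, while PHO87 was at -0.12 ± 0.1 (adjusted p = 0.372). In all, 16 of 22 PHO regulon genes fell and 2 rose (17 and 3 when adjusted over the list alone).

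Among the genes that rose, NRD1 and IMD2, which are held down by early termination, were at 1.60 ± 0.114 and 1.09 ± 0.0932, and 4 of 8 genes of that kind rose with none lower (4 when adjusted over the list alone). Of 17 other genes for the exosome and its cofactors 8 rose and none fell (8 when adjusted over the list alone), led by the poly(A) polymerase gene TRF5 at 1.37 and AIR2 at 0.75. Early meiosis genes were higher for 10 of 21 and lower for 3 (10 and 4 when adjusted over the list alone), with MEI4 rising 13.4-fold and RED1 4.36-fold. Of 17 glucose-repressed genes 12 rose and 1 fell (13 and 2 when adjusted over the list alone), among them the malate synthase gene MLS1 at 3.07 ± 0.133 and the regulator gene SIP4 at 2.00 ± 0.214 (SE). INO1, the inositol synthesis gene, rose 7.2-fold and TIS11, an mRNA-binding protein gene of the iron response, 5.37-fold. Among the genes that fell were YNL040W at -2.01, the methyltransferase gene TMT1 at -1.69, the hexokinase gene HXK1 at -1.64, HOR7 at -1.41 and SOL4 at -1.39. General stress genes fell for 26 of 37 and rose for 2 (28 and 2 when adjusted over the list alone). Of 31 Gcn4 amino acid genes 26 fell (26 when adjusted over the list alone), with ARG1 at -1.22 and ARG4 at -1.14, and 17 of 31 respiration genes fell and 1 rose (18 and 1 when adjusted over the list alone). OPI3, a phospholipid synthesis gene, fell by 1.09 on the log2 scale. IMD2, AIR2 and OPI3 overlapped the levels of the 5 BY4741 libraries at 7.2 mM, while the other genes named in this paragraph lay outside them. Whether strand was used in counting is not given. A rise of a gene named in this or the preceding paragraph can therefore also hold reads of antisense or overlapping transcripts, which was not tested. Features listed as ribosomal RNA took 1.93% and 2.16% of reads in the rrp6 deletion libraries and 0.0804% in BY4741.

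In total 2449 of 6039 genes passed, 963 higher and 1486 lower, 262 of them at least 2-fold higher and 42 at least 2-fold lower. The median gene was at -0.0777, and at -0.11 after TMM scaling. Camera gave limma-based adjusted p of 0.000129 for the PHO regulon, 2.62e-08 for general stress, 2.53e-08 for Gcn4 genes, 4.82e-06 for glucose-repressed genes and 0.00754 for respiration, with adjusted p = 0.474, 0.474, 0.525, 0.474 and 0.474 with an estimated correlation. For the exosome, early termination and early meiosis lists the adjusted p was 0.00187, 0.00473 and 0.00232 (limma with camera), and adjusted p = 0.505, 0.507 and 0.569 with an estimated correlation.

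**Figure D4:**
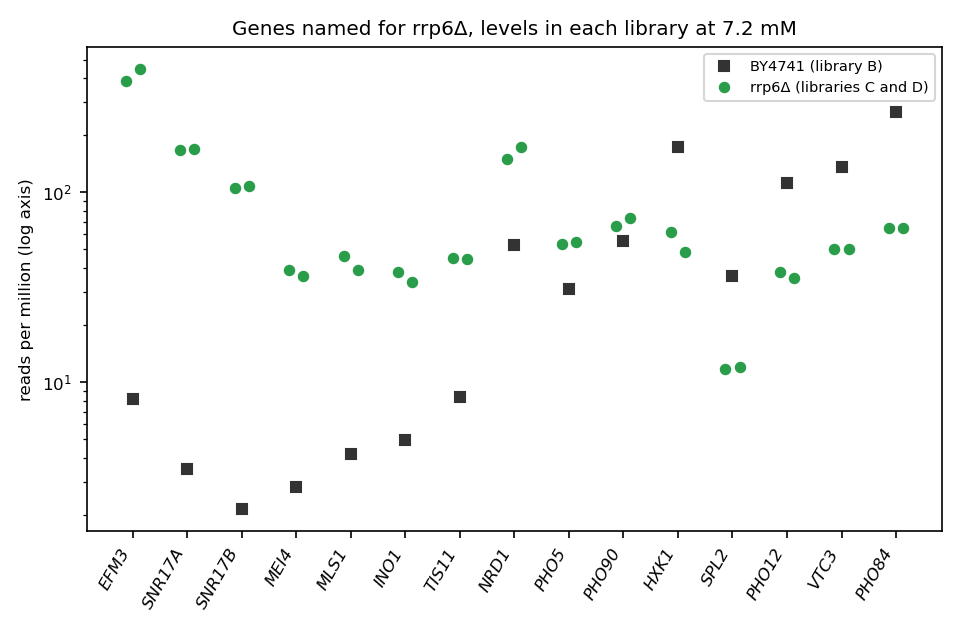
RPM on a log axis for 15 genes in BY4741 (square) and in both rrp6 deletion libraries (circles) of experiment 2 at 7.2 mM phosphate. SNR17A reached 168 as a mean of both deletion libraries against 3.51, and PHO84 lay at 64.7 against 263.4.

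Loss of the block P segment upstream of SPL2 was measured in a single pair of libraries, so no difference has a replicate check and none was tested. SPL2 stood at 33.8 RPM in the deleted strain and 23.5 RPM in BY4741, a ratio of 1.44 (95% interval 1.32 to 1.56), and the level in the deleted strain lay within the 20.21 to 36.08 RPM of the 5 BY4741 libraries at 7.2 mM. PHO84 had a ratio of 1.42 (1.39 to 1.46), at 353.9 against 248.7 RPM, above the highest of the 5 BY4741 libraries at 263.4 RPM. PHO5 was at 15.8 against 17.1 RPM, a ratio of 0.921 (0.826 to 1.03), and the ratios of PHO87 and PHO90 were 0.994 (0.942 to 1.05) and 1.07 (1.02 to 1.12). Leaving out features of the ribosomal DNA repeat as multi-copy, YOR338W had the highest ratio at 10.2, from 6.56 to 66.9 RPM, followed by PRM7, a pheromone-regulated gene, at 6.62, YBR056W-A at 5.05, YJL107C at 4.56 and DIA1, a gene of filamentous growth, at 3.96. The glycogen synthase gene GSY1 had the lowest ratio at 0.383 (0.347 to 0.422), followed by the trehalose synthesis gene TSL1 at 0.530, GPH1 at 0.566, the phosphoglucomutase gene PGM2 at 0.588 and LEU1 at 0.599. GPH1 and PGM2 lay within the levels of the 5 BY4741 libraries.

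Of 4210 features with at least 30 RPM in either library of this pair, 36 were at least 2-fold higher in the deleted strain and 1 was at least 2-fold lower. The higher ones include features of the ribosomal DNA repeat, whose reads cannot be assigned. Of 22 PHO regulon genes 16 were higher, and the list median of 0.28 on the log2 scale lay at percentile 100 among 10000 random lists matched on level. Ribosome biogenesis genes had a median of 0.23 (55 of 59 higher, percentile 100), hexose transporter genes 0.60 (5 of 7 higher, percentile 100), small nucleolar RNAs 0.57 (31 of 34 higher, percentile 100) and glycolysis genes 0.12 (14 of 16 higher, percentile 100). The medians of heat shock chaperone genes at -0.33, general stress genes at -0.17 and purine synthesis genes at -0.19 lay at percentile 0. Other lists also lay near the ends, such as exosome genes at 99.8, glucose-repressed at 99.5, Gcn4 at 0.06 and respiration genes at 0.02. The random lists hold genes drawn independently, so genes that move together can place a list at an end. The percentiles are therefore no test of a list. Features listed as ribosomal RNA took 0.704% of reads in the deleted strain and 0.198% in BY4741, so the libraries also differed in RNA composition, and these values compare 2 libraries, not the conditions.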

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

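The tests of the response slopes, of the second BY4741 reference, of the range of the BY4741 libraries, of TMM scaling and of the ribosomal protein share were chosen only after the result was seen; the test without library 12 and the splits of the libraries were set beforehand.

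The phosphate response differed between BY4741 and the spl2 deletion in 882 genes by the interaction test, which is what drew attention to these results. The differences, spl2 deletion minus BY4741, were 2.60 for PHO84, 1.23 for VTC3, 0.98 for PHO12, 0.84 for AQR1, 0.81 for VTC4, 0.69 for DBP2, 0.64 for NSR1, 0.60 for ENP2, 0.59 for UTP10, 0.45 for SHM2, 0.42 for ADE6, 0.30 for PHO87 and 0.27 for PHO90. On the other side they were -0.74 for PHO5, -0.92 for ARO9, -1.01 for HOR7, -1.08 for CYC7, -1.09 for RTC3 and -1.22 for HSP12. ARO9 neighbours the deleted SPL2, and a local effect of the deletion on it was not tested. Lists called by camera had median differences of -0.66 for general stress, 0.44 for ribosome biogenesis, 0.30 for purine synthesis, 0.14 for the exosome, 0.11 for Gcn4 genes, -0.0865 for ribosomal proteins and -0.12 for respiration. None of these 7 held with an estimated correlation (adjusted p = 0.117, 0.361, 0.245, 0.361, 0.901, 0.901 and 0.361 in the same order). For the count of 4068 genes in BY4741 and the count of 789 between the strains at 0 mM, 1 of 10 splits of the 6 libraries, the real one, gave as many genes and the highest other count was 0, but 10 splits are too few for a share under 0.05.

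General stress genes were lower in the spl2 deletion without phosphate. A smaller response of every gene would give the same ratio of responses in all lists. The slope of the spl2 deletion on the BY4741 response was 0.105 (95% interval 0.0177 to 0.177) over 37 stress genes. It was 1.14 (0.987 to 1.32) over 21 PHO genes, a difference of -1.04 (-1.23 to -0.86). The intervals come from resampling genes, so they treat co-regulated genes as independent and leave out the spread between cultures. The unequal slopes argue against a smaller response of every gene, but the intervals do not test this between cultures. A wrong label on spl2 deletion library 12 is conceivable, given the conflict between the series description and the labels. Leaving that library out cannot show whether its label is right, only whether the stress result rests on it. A wrong label as the cause of the stress result is argued against by the median difference of the phosphate responses over the stress list. That median was -0.68 without the library (-0.75 to -0.60 without each library in turn). It is not the difference at 0 mM alone, since the list median between the strains was -0.37 at 0 mM and 0.29 at 7.2 mM. PHO84 stood at 2346, 2151 and 2194 RPM in libraries 12, 19 and 20 and at 29.4 and 33.1 RPM in libraries 7 and 18, and PHO5, VTC3 and VTC4 divided the libraries in the same way, so the levels of these genes follow the sample labels of all 5. What stays open is an effect of the SPL2 deletion, as a hypothesis, against a difference between cultures in how the stress genes reacted to washing, which no table here tests.

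Most tested genes were called in the bmh1 deletion library. Scaling to the library total is argued against as the whole cause of that number, since 57.9% of tested genes were still called after TMM scaling (3469 against 3832), although the directions moved. A library batch shared with experiment 2 could account for most of the calls. Of the 3832 genes 25% kept at least 50% of their change in the same direction against BY4741 of experiment 2. This compares single libraries without a test. Over 5630 genes the differences of the bmh1 deletion library and of BY4741 of experiment 2 from BY4741 of experiment 1 had Pearson r = 0.658. A simulation without any effect, in which both shared that reference, gave 0.25. The shared batch is argued against for PHO84 and SPL2. The smaller of their falls from the lowest of the 5 BY4741 libraries of 3 experiments was -2.65, while those libraries spanned 0.476 and 0.806 on the log2 scale. For these genes an effect of the BMH1 deletion stays open as a hypothesis that rests on 1 library.

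More genes were higher than lower without phosphate in BY4741, 90.1% of the called genes. TMM scaling left 46.9% higher, but it centres the genes by construction and so decides nothing. With ribosomal protein genes left out of the library totals the median log2 fold change was 0.0812 against 0.21, which is consistent with the smaller share of ribosomal protein reads as a main part of the excess. Whether the amount of mRNA per cell changed cannot be read from these data, and no biological explanation was tested.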

How the results depend on the processing

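The TMM, edgeR and DESeq2 fits, the second reference for the bmh1 deletion and the PHO regulon without SPL2 were chosen after the data were seen; the other settings were planned. For the BY4741 phosphate response the count of 4068 genes became 2311 after TMM scaling, 2276 with edgeR and 2170 with DESeq2, and for the spl2 deletion 3984 became 2643 with edgeR and 2525 with DESeq2, which both centre the genes. The spl2 deletion at 7.2 mM gave 30 genes, but 81 with the compared groups alone and 112 with DESeq2. The bmh1 deletion gave 3832 genes and 1117 against the second reference, a count without replicates on either side that is not used elsewhere. Leaving out each library gave 16 to 65 genes for the spl2 deletion at 7.2 mM, 228 to 914 at 0 mM and 506 to 1080 for the strain difference; each such fit has fewer libraries.

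The number of gene lists called by camera, 11 for the BY4741 phosphate response, became 3 with an estimated correlation and 21 with fry, which asks a different question. For the spl2 deletion phosphate response 8 lists became 0 and 19, and for the bmh1 deletion 10 became 0 and 25. With an estimated correlation 1 list was left of 9 for the spl2 deletion at 7.2 mM, the PHO regulon with the deleted SPL2 included (adjusted p = 0.0564 without it), and 0 for the spl2 deletion at 0 mM, the strain difference and the rrp6 deletion.

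PHO90, PHO84 and BMH2 changed sign under some setting. PHO90 in the phosphate response of the spl2 deletion went from 0.22 to -0.01133 after TMM scaling, -0.01348 with edgeR and -0.00799 with DESeq2, which remove the shared shift of all genes by construction. PHO84 between the strains at 0 mM, at 0.00177, ranged from -0.03522 to 0.02736 when single libraries were left out, around a difference that did not pass. In the bmh1 deletion BMH2 went from -0.38 to 0.07166 and PHO90 from -0.52 to 0.06688 against the second reference, and the cause was not tested. RLE size factors in edgeR, written down for read counts, were not run, and scaling by library totals for the promoter pair is what RPM already is. No paired analysis was possible because the labels give no replicate number shared between the phosphate levels, although by the growth protocol an overnight culture served both levels.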

Other observations

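The comparisons of markers and of BY4741 levels across experiments below were chosen only after the result was seen; the tests of the genes that rose in the rrp6 deletion were set before.

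PHO84 and SPL2 were lower together in the bmh1 and rrp6 deletions with phosphate. In the bmh1 deletion PHO84 was 6.6-fold and SPL2 9.12-fold lower, and in the rrp6 deletion 4.07-fold and 3.03-fold lower than in BY4741 of the same experiment, or 2.92-fold and 1.7-fold lower than in the lowest of the 5 BY4741 libraries. In the spl2 deletion, which had 0 SPL2 reads with phosphate, PHO84 was 6.18-fold lower. PHO5 fell in the bmh1 deletion with a log2 fold change of -0.51 (limma adjusted p = 0.00593, and 0.145 after TMM scaling), rose in the rrp6 deletion with 0.78 (adjusted p = 0.000518) and did not pass in the spl2 deletion at -0.23 (adjusted p = 0.4). Whether the PHO84 change in the bmh1 and rrp6 deletions runs through SPL2 was not tested.

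The 262 genes that rose at least 2-fold in the rrp6 deletion were examined for simpler causes. Genes next downstream of a small nucleolar or small nuclear RNA gene were among them for 2 of 59 against 210 of 5664 other genes (odds ratio 0.911, 95% interval 0.107 to 3.49), which is too wide to tell; the raised neighbours were YDR042C at 2.39 and PMD1 at 2.02. Of the 262 genes 68.3% had at least 10 RPM in both deletion libraries, which did not decide whether low read numbers were a cause. That cut lies far above the floor of 3 reads, 0.16 and 0.172 RPM in these libraries, so the other genes need not have few reads. Of the same genes 46 were absent from the reference names, 17.56% against 5.1% of tested features.

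BY4741 and the promoter strain of experiment 3 differed from the other experiments in genes outside the comparison. ARO10, a decarboxylase gene of aromatic amino acid breakdown, ranged from 36.3 to 50.7 RPM in experiments 1 and 2 and was at 0.963 RPM at the lowest in experiment 3. MFA1, the a-factor gene, ranged from 52.7 to 117 RPM in experiments 1 and 2 and reached 439 RPM in experiment 3. IME4, at 19.55 to 61.59 RPM in experiments 1 and 2, was at 0.291 and 0.1094 RPM in experiment 3. BUD28 went from 179.2 to 860.3 RPM down to 0.3358 and 0.3555 RPM, and MFA2 from 92.52 to 185.9 RPM up to 606.2 and 498.2 RPM. MF(ALPHA)2, a gene of mating type alpha, stood at 6.07 to 8.9 RPM in experiments 1 and 2, although BY4741 is of mating type a. In experiment 3 it stood at 0.06716 and 0.08204 RPM. SAG1, of the same list, stood at 17.5 RPM or more in all 17 libraries. Whether strand was counted alike in the experiments is not given, so a difference in counting cannot be told apart from one in transcription. The cause was not tested.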
